A study of Mus musculus with 8 samples.

How the data were processed

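Mammary tumours of mice that carry both an s-SHIP promoter-GFP reporter and the C3(1)-Tag transgene were profiled on arrays of total RNA labelled with Cy3. The reporter places GFP under the internal promoter of Inpp5d, which gives the short SHIP1 isoform of stem cells, and the Tag transgene expresses the SV40 large T antigen, which binds p53 and the retinoblastoma protein. Per the labels' protocols, tumours were dissociated enzymatically with a mouse tumour kit and the single cells were sorted by flow cytometry on GFP and CD49f, the protein of Itga6. The labels name 2 sorted populations, lineage-negative CD49f-positive cells with GFP and the same cells without it, and give no list of the lineage antibodies. The titles give each population the numbers 566, 567, 573 and 631, so that 8 arrays form 4 pairs. A number is taken here to mark a tumour. The labels do not say that each came from a separate animal, and if some did not, p-values measure only the spread between these samples.

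The deposited values are spot intensity on a linear scale, 1 array per sample, made with Agilent Feature Extraction 10.7.3.1 per the file headers and the submitters' processing notes. Per the file headers, the processed intensity had been background-subtracted and detrended across the array and had not been normalized between arrays. The deposited series-wide table held intensity equal to that processed intensity in all 62976 spots of each of the 8 arrays, linear, not centred and not a ratio, with column medians from 23.6 to 36.6. All arrays came from 1 slide and 1 scan. Of the slide's columns, 1 held all 4 arrays of GFP-positive cells and the other all 4 arrays of GFP-negative cells, so slide column and population cannot be told apart. No other columns of per-sample values were present.

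Each array held 59305 gene spots. Control spots and spots with outlier flags were left out and spots of a probe were averaged, which kept 56555 of 56605 gene probes; 50 had lost their spots on an array. Accessions in the files were matched without versions to a RefSeq gene table of assembly GRCm38.p6, used for names alone. This gave 32969 probes a symbol from among 22904 symbols, and the other 23586 kept the name in the files. No coordinates are given, because no genome of the build used for the array was used here.

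Processed intensity was put on the log2 scale and each array's 75th percentile was subtracted, so that a level of 0 is that percentile. Levels of different probes are not compared. Probes well above background on all 4 arrays of at least 1 population were kept, and of several probes of a gene the one with the highest mean over the 8 arrays was used. This left 26316 probes and 20265 genes, 13318 of them with a symbol and 6947 without. Of 4859 genes with more than 1 passing probe, 1715 had a probe of opposite sign, and in 0 of them did both exceed 1 on the log2 scale. A gene dim on every array of a population would be given as an at-least fold, the bright mean over a floor made of the lowest signal well above background; no gene named here needed one.

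Differences are GFP-positive minus GFP-negative on the log2 scale, tested with limma 3.58.1 in R 4.3.3 without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each SE given comes from this fit, so it holds the spread between tumours as well as that within pairs. The design, 37 gene lists and the alternatives were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 33 lists tested, and again with an estimated correlation and with fry. List names stand for their members alone. The genes named are of 3 kinds: where fewer than 5 genes passed in a direction, the 10 with a symbol, the same direction in all 4 pairs and the smallest unadjusted p; up to 4 members with the smallest p from a list that shifted and 2 from another list; and Inpp5d, Itga6, Ptprc, Krt5, Krt14, Trp63, Krt8, Krt18, Epcam, Cd24a, Procr and Cd44. Predicted genes were not named.

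The numbers pair the arrays. Deviations of same-numbered arrays from their population means correlated across genes at 0.573, 0.695, 0.642 and 0.741 for 566, 567, 573 and 631, against at most 0.221 with any other number. This was decided before fits with the number as a block were looked at. Alternatives were quantile and median scaling, normexp with an offset of 50, other filters on dim probes, the tumour as a fixed or random block, another variance model, array weights, other handling of several probes, other thresholds, and each array and each tumour left out. Others were added after the data were seen: a filter of 3 of 4 arrays, a percentile over probes detected on all 8 arrays, a common floor with and without the block, the block without tumour 631, and the mammary stem and cap cell list without Inpp5d, with and without the block. A threshold of 0.1 on the adjusted p with the random block was also added then. The common floor raised lower values on all arrays to the highest of the arrays' floors, that of the GFP-positive array of tumour 573.

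The procedure was tested on simulated data for the 20265 genes of this comparison. Without the block it recovered 2.99% of genes changed 2-fold, 50.7% of those changed 4-fold and 84.8% of those changed 8-fold, with 0 false calls. With the block it recovered 38.8%, 76.1% and 97.0%, with 7 false calls. A shifted list was called in both fits and 0 of 20 unchanged lists were. The simulated noise was independent between genes and the lists held genes drawn at random. This therefore does not test list calls where members are correlated. In the real lists that shifted, the estimated correlation ran from -0.031 for mammary stem and cap cell to 0.843 for interferon response genes. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.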

Results

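The 8 arrays measured RNA of GFP-positive and GFP-negative sorted cells of 4 mouse mammary tumours, 4 arrays per population. On 7 arrays between 53.5% and 58.5% of gene spots were well above background. The array of GFP-positive cells of tumour 573 had 34.1%, and its lowest signal well above background was 142 intensity units against 13.4 to 23.5 on the others. The 75th percentile of intensity ran from 344 to 580 units. All GFP-positive arrays lay in 1 slide column and all GFP-negative arrays in the other. Tumours differed more than populations did. The tumour accounted for 76.6% of the variance of the 20265 genes tested, the population for 7.11% and the rest was 16.3%. These are shares of the sum of squares. The tumour and the rest hold more degrees of freedom than the population, so the population's share cannot be set directly against the rest. The first principal component held 49.9%.

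The design compares cells that express GFP from the reporter with cells of the same gate that do not. Inpp5d, the gene whose internal promoter drives the reporter, had a level of -1.62 ± 1.11 (SD, n = 4) in GFP-positive cells and -3.60 ± 0.83 (SD, n = 4) in GFP-negative cells. The difference was 1.98 (SE 0.59), with 2.75, 1.68 and 2.23 in tumours 566, 567 and 631. In tumour 573 it was 1.28, but there the GFP-positive array did not measure Inpp5d well above background, so that its raised background can give that value and sign. The place of the Inpp5d probe relative to the internal promoter was not examined, so which SHIP1 isoform it measured is not known. Itga6, the gene of the sort marker CD49f, differed by 0.08 (SE 0.36), and by -0.03 with median scaling or normexp; its other probes gave -0.06 and -0.75. The simple-epithelial keratins Krt8 and Krt18 differed by 0.25 (SE 0.35) and 0.13 (SE 0.27). Trp63, a transcription factor of basal epithelium, differed by 0.02 (SE 0.21), and by -0.08 with median scaling and -0.06 with normexp.

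The basal keratins Krt5 and Krt14 had mean differences of 1.33 (SE 1.24) and 1.16 (SE 0.92), and the epithelial surface genes Epcam and Cd24a of 1.20 (SE 1.06) and 0.74 (SE 0.87). The differences in tumour 631 were 3.99, 4.26, 4.0 and 3.16, and without its GFP-negative array they were 0.70, 0.20, 0.0028 and -0.15; without the GFP-positive array of 566 that of Krt5 was 0.38. Procr, a surface marker used for mammary stem cells, differed by 0.59 (SE 1.35), by -0.15 after quantile normalization and by -0.35 without the GFP-negative array of 573. Cd44 differed by -0.27 (SE 0.54), another of its probes by 0.58, and without the GFP-positive array of 573 it differed by 0.29. Ptprc, the pan-leukocyte gene, was not well above background on any array, by 2 probes. None of these genes passed the test.

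**Figure D1:**
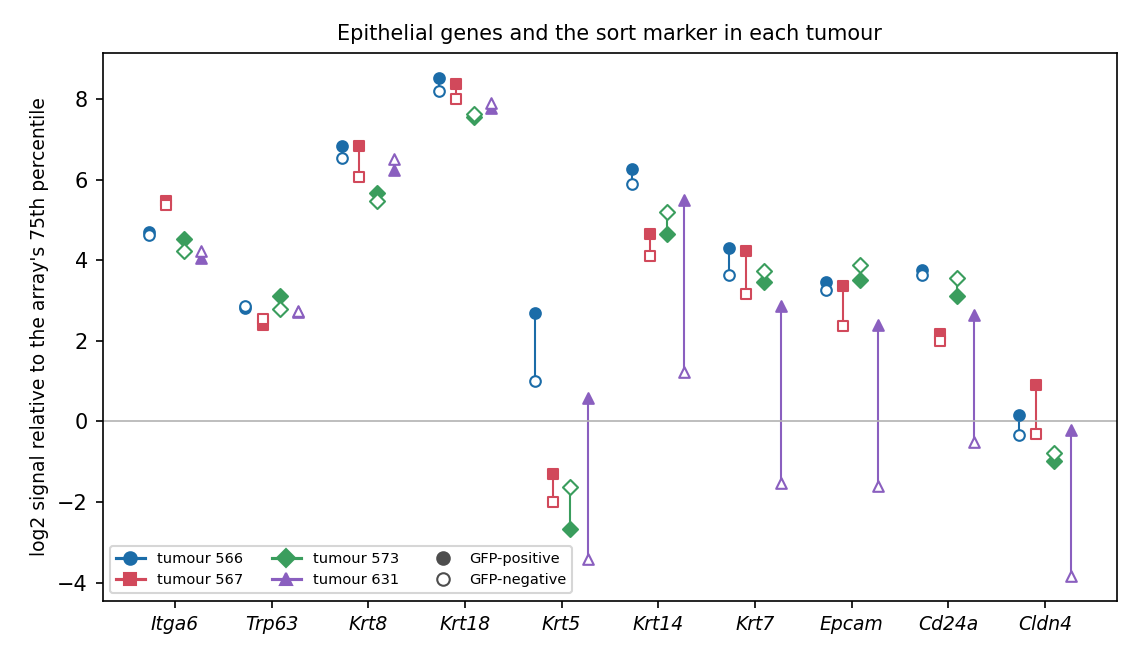
Log2 signal relative to each array's 75th percentile (vertical axis) for 10 genes (horizontal axis), with filled points for GFP-positive and open points for GFP-negative cells and a line joining both populations of a tumour. Krt14, Epcam and Krt7 lay 4.26, 4.0 and 4.41 lower in GFP-negative than in GFP-positive cells of tumour 631, while Krt8 and Krt18 differed by -0.29 and -0.11 there.

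Among single genes, those with the smallest p and a higher value in GFP-positive cells of all 4 tumours were Gzme, a granzyme of cytotoxic cells, at 4.95 (SE 1.13), Acod1, Inpp5d, Ccng1, Bdh1, Trp53inp1, Mmrn2, Vwf, Cdh3 and Lyzl6. For Acod1, Inpp5d, Mmrn2, Vwf and Lyzl6 the value of the GFP-positive cells of tumour 573 was not well above the raised background of that array, so that the higher value there may come from that background; without that array Inpp5d differed by 2.53. Gzme differed by 6.45, 2.60, 5.87 and 4.87 in the 4 tumours and was well above background on 1 of 4 GFP-negative arrays, so that the size of its difference rests mostly on signal not told from background. The p53 targets Ccng1 and Trp53inp1 differed by 0.79 (SE 0.23) and 0.79 (SE 0.25), and Acod1, which makes itaconate, by 1.27 (SE 0.33). The endothelial genes Mmrn2 and Vwf differed by 3.30 (SE 1.07) and 2.03 (SE 0.67), with 6.71 and 4.53 in tumour 566. Cdh3, P-cadherin, differed by 2.69 (SE 0.90), with 7.14 in tumour 573, and was well above background on 2 of 4 GFP-negative arrays, not on that of 573, so that the 7.14 rests on signal not told from background; without tumour 573 it differed by 1.20. Bdh1 and Lyzl6 differed by 1.14 (SE 0.35) and 0.57 (SE 0.19).

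Of the 10 such genes lower in GFP-positive cells, 7 make structural non-coding RNAs. They were the RNase P RNA Rpph1 at -1.25 (SE 0.23) and its relatives Rprl1, Rprl2 and Rprl3 at -1.46, -1.53 and -1.66, Rmrp at -1.45 (SE 0.28), Rn7sk at -1.39 (SE 0.23) and the signal recognition particle RNA Rn7s1 at -1.04 (SE 0.20). The other genes were Rgs5 at -2.85 (SE 0.47) and Higd1b at -2.83 (SE 0.43), both pericyte markers, and Dlk1, a Notch-family ligand, at -2.13 (SE 0.44). Rgs5 differed by -1.93, -3.21, -4.39 and -1.86 in the 4 tumours. Rgs5, Higd1b, Dlk1 and the 3 Rprl genes were well above background on 3 of 4 GFP-positive arrays, not on that of 573.

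**Figure D2:**
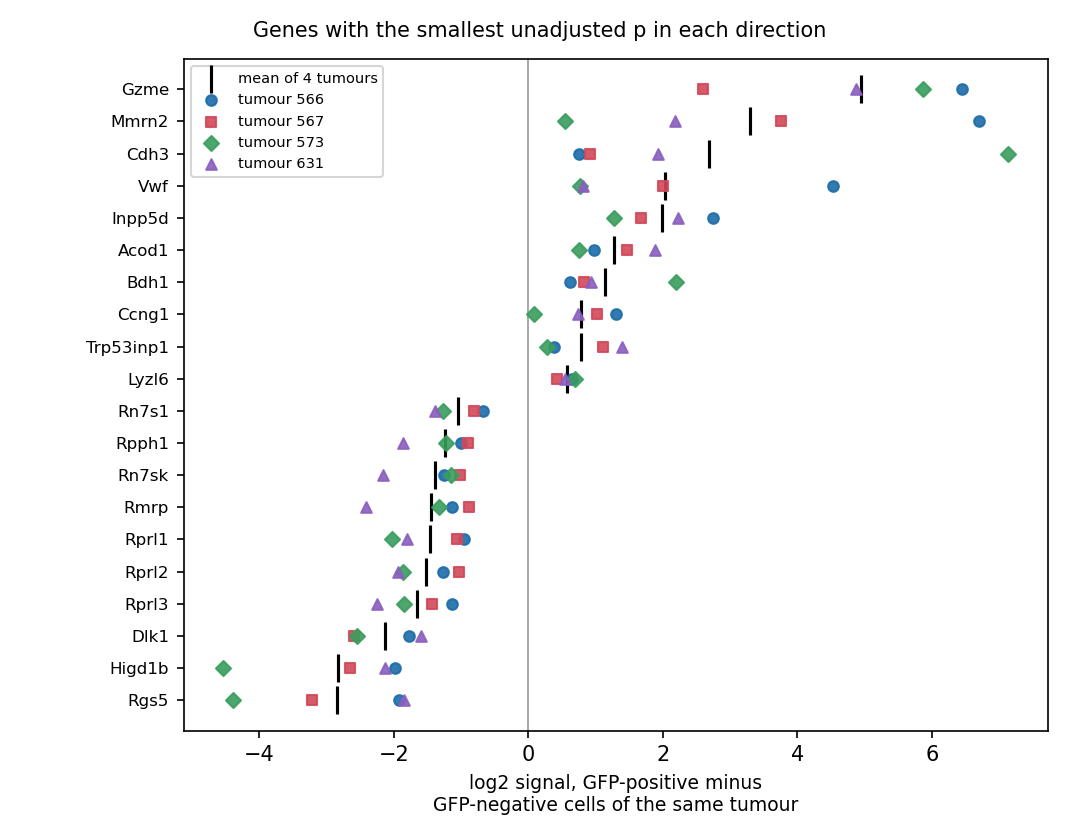
Log2 difference between GFP-positive and GFP-negative cells (horizontal axis) for the 10 genes per direction with the smallest unadjusted p (vertical axis), with a coloured point per tumour and a bar at the mean of 4 tumours. The genes shown were chosen for 4 points on the same side of 0; for Acod1, Inpp5d, Mmrn2, Vwf and Lyzl6 the point of tumour 573 rests on a GFP-positive value not well above background. Gzme has a mean of 4.95 and was well above background on 1 of 4 GFP-negative arrays.

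None of these genes passed limma's test. Of the 117 named genes measured, 81 moved by over 1.5 times or turned when 1 array was left out, and 48 were not well above background on the GFP-positive array of 573, so that single differences given here and below hold as means of these samples alone. Over 20265 genes, limma called 0 at an adjusted p under 0.05 and 0 with at least a 2-fold change, with a smallest adjusted p of 0.675. At an unadjusted p under 0.05 there were 161 genes, 46 higher and 115 lower, where chance gives 1013 if the arrays are independent. The arrays are paired, and this fit leaves the differences between tumours in its residual, so fewer are reached. Other splits of the arrays that part all 4 pairs gave at most 129, so 161 against 1013 does not measure a lack of signal. With the tumour as a fixed block the calls were also 0, with 1113 genes at an unadjusted p under 0.05, 332 higher and 781 lower, and a smallest limma adjusted p of 0.459. With the tumour as a random block they were 0 and 1005, with a smallest limma adjusted p of 0.0532. The same direction in all 4 tumours was seen for 2885 genes, 14.2%, where chance gives 12.5%.

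Of the 33 gene lists tested, camera called 15 shifted, 11 higher and 4 lower in GFP-positive cells, and the same 15 with the tumour as a block. With an estimated correlation 1 list stayed called, the pericyte markers, and fry called that list alone; with the block, an estimated correlation and fry called 0. Members passing the test numbered 0 when adjusted over all genes; adjusted over the list alone they numbered 3, all in the pericyte list, or 15 over all lists with the block. In all other lists the number adjusted over the list alone was 0 without the block.

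Pericyte markers fell as a list. All 12 were measured, 11 were lower on average and 7 were lower in all 4 tumours. The mean difference was -1.28, with tumour means of -0.96, -1.64, -1.79 and -0.72. The list's adjusted p was 4.94e-12 with camera, 0.0115 with camera at an estimated correlation and 0.0457 with fry. Rgs5, Higd1b and Gucy1a1, a guanylate cyclase subunit of contractile cells, passed without the block when adjusted over the list alone, and 7 members did with it. Gucy1a1 differed by -1.99 (SE 0.49). Des, desmin, differed by -1.11 (SE 0.52). With the tumour as a block the call was lost with an estimated correlation, at an adjusted p = 0.582. With a common floor the mean was -0.79.

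Macrophage and monocyte markers fell as a list, with 7 of 15 measured, 6 lower and a mean of -0.70 (camera adjusted p = 8.50e-05; adjusted p = 0.206 with an estimated correlation). The complement genes C1qa and C1qb differed by -1.95 (SE 1.03) and -0.82 (SE 0.38), Aif1 by -0.85 (SE 0.33) and Fcer1g by -0.80 (SE 0.49). C1qa was measured well above background on 2 of 4 GFP-positive arrays. With a common floor, that of the GFP-positive array of 573, the mean was -0.17. That array's lowest signal well above background was 142 intensity units, against 13.4 to 23.5 on the others. Most of the size of this shift thus rests on signal below that raised floor. C1qb, Aif1 and Fcer1g were well above background on every other array. With the floor and the block the call was lost, at a camera adjusted p of 0.388.

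Hypoxia and glycolysis genes fell as a list, with all 26 measured, 25 lower and a mean of -0.35 (camera adjusted p = 0.000125; adjusted p = 0.647 with an estimated correlation). Vegfa differed by -0.74 (SE 0.41), Adm by -0.77 (SE 0.53), P4ha1 by -0.71 (SE 0.43) and Ankrd37 by -0.52 (SE 0.29). Tumour means were 0.10, -0.11, -0.94 and -0.43. The call was lost without the GFP-positive array of 573, where the mean was -0.08 and the camera direction turned (adjusted p = 0.989), without the GFP-negative array of 631 (0.0774) and without tumour 573 (0.126). Genes of S phase and DNA replication fell as a list by a mean of -0.13, with 29 of 32 lower (camera adjusted p = 0.0243; adjusted p = 0.672 with an estimated correlation). Cdt1, which loads the replicative helicase, differed by -0.34 (SE 0.29), Cdc6 by -0.28, E2f1 by -0.25 and Mcm10 by -0.19. That call was lost without the GFP-positive arrays of 567 (0.156) or 631 (0.239), the GFP-negative arrays of 573 (0.293) or 631 (0.509), tumours 573 (0.126) or 631 (0.702), and with the block after quantile normalization (0.784).

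The luminal epithelial list and the cell adhesion and tight junction list rose, mostly in tumour 631. Luminal epithelial genes had a mean of 0.90, with 20 of 20 measured members higher (camera adjusted p = 6.82e-11; adjusted p = 0.307 with an estimated correlation), and cell adhesion and tight junction genes a mean of 0.85, with 21 of 23 higher (camera adjusted p = 3.41e-12; adjusted p = 0.307 with an estimated correlation). Tumour means were 0.35, 0.69, -0.11 and 2.66 for the luminal list and 0.16, 0.61, 0.25 and 2.40 for the adhesion list. Krt7 differed by 1.47 (SE 1.10), the claudins Cldn4 and Cldn1 by 1.27 (SE 0.79) and 1.08 (SE 0.61), Muc1 by 1.17 (SE 0.77), Aldh1a3 by 1.13 (SE 0.69) and the plakophilin Pkp3 by 0.74 (SE 0.46). Without the GFP-negative array of 631 the means were 0.10 (adjusted p = 0.131) and 0.17 (adjusted p = 0.286).

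Basal and myoepithelial keratins and contractile genes rose as a list by 0.46, with 18 of 22 higher (camera adjusted p = 3.54e-05; adjusted p = 0.206 with an estimated correlation). Lama3, a laminin chain, differed by 1.75 (SE 1.05), Tagln by 0.69 (SE 0.50) and Mylk, myosin light chain kinase, by -1.32 (SE 0.67) with lower values in all 4 tumours. Without the GFP-negative array of 631 Lama3 differed by 0.65 and Tagln by 0.29 and the list's adjusted p was 0.0774, and with the block and without tumour 631 it was 0.0533. The squamous and hair follicle keratinocyte list rose by 0.28, with 8 of 12 higher (camera adjusted p = 0.00663; adjusted p = 0.206 with an estimated correlation). Krt6a differed by 1.13 (SE 0.67), Klk6 by 0.64, Sprr1a by 0.65 and Lor by 0.41. Its call was lost without the GFP-positive arrays of 566 (0.136) or 631 (0.152), the GFP-negative array of 573 (0.0812) or tumour 631 (0.0792), with the block and without tumour 631 (0.127), and with the block and a common floor (0.051).

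The mammary stem and cap cell list rose by 0.30, with 9 of 15 higher (camera adjusted p = 0.0191; adjusted p = 0.206 with an estimated correlation). With Inpp5d left out, a step added after the data were seen, the mean was 0.18 and the call was lost (camera adjusted p = 0.163; 0.267 with the block). Beside Inpp5d it held Gas6 at 1.23 (SE 1.10), which was 0.047 without the GFP-negative array of 631, Gng11 at 0.43 (SE 0.36) and Sox9 at -0.46 (SE 0.33). The call was lost without the GFP-positive arrays of 566 (0.109), 567 (0.237) or 631 (0.0824), the GFP-negative arrays of 566 (0.0545), 573 (0.162) or 631 (0.0774), and tumours 566 (0.147) or 567 (0.0524). It was also lost with the block after quantile normalization (0.0857) and with the block and a common floor (0.135).

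The fibroblast and endothelial marker lists rose, with means that differed in sign between tumours. Fibroblast markers had a mean of 0.55, with 8 of 12 higher (camera adjusted p = 0.00782; adjusted p = 0.647 with an estimated correlation) and tumour means of 1.83, -0.36, -0.52 and 1.24. Mfap5, a microfibril protein, differed by 2.98 (SE 1.62), Clec3b by 0.97, Dcn by 1.04 and Thy1 by -1.37; without the GFP-negative array of 573 Dcn differed by 0.40, and without the GFP-positive array of 573 Thy1 differed by -0.24. Endothelial markers had a mean of 0.64, with 5 of 7 higher (camera adjusted p = 0.0168; adjusted p = 0.614 with an estimated correlation) and tumour means of 2.91, 0.35, -0.68 and -0.04. Plvap differed by 1.54 (SE 1.10), Emcn by 1.68, Egfl7 by 0.82 and Eng by 0.59, and without tumour 566 Emcn differed by -0.02 and Eng by -0.10; without its GFP-positive array Egfl7 differed by -0.19. Pecam1 was measured well above background on 3 of 4 arrays in each population and was not tested.

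Interstitial matrix and remodelling genes rose as a list by 0.34, with 16 of 26 higher (camera adjusted p = 0.00187; adjusted p = 0.672 with an estimated correlation); Tnc, tenascin, differed by 1.25 (SE 0.71), Col5a2 by 1.10, Col12a1 by 1.08 and Lox by 1.22. Lox differed by 3.45, -0.33, 2.25 and -0.48 in the 4 tumours and by 0.47 without the GFP-negative array of 573, Col12a1 by 0.69 without the GFP-positive array of 566 and Tnc by 0.63 without the GFP-negative array of 631. Without the GFP-positive array of 566 the fibroblast mean was 0.08 (adjusted p = 0.417), the endothelial mean -0.06 (0.738) and the interstitial matrix adjusted p 0.136. The fibroblast markers call was also lost without the GFP-positive arrays of 567 (0.156) or 631 (0.22), the GFP-negative arrays of 573 (0.682) or 631 (0.0774), tumours 566 (0.255) or 631 (0.304), and with the block without tumour 631 (0.142). The endothelial markers call was also lost without the GFP-negative arrays of 566 (0.061), 573 (0.0642) or 631 (0.176), the GFP-positive array of 567 (0.12), and with the block after quantile normalization (0.0783); without tumour 566 the mean was -0.12 (0.64). The interstitial matrix call was also lost without the GFP-positive arrays of 567 (0.197) or 631 (0.264) and tumour 631 (0.0834; 0.0891 with the block), and without the GFP-negative array of 573 its mean was -0.11 (0.723).

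Interferon response genes rose as a list by 0.24, with 20 of 22 higher (camera adjusted p = 0.00791; adjusted p = 0.751 with an estimated correlation). The tumour means were 0.12, -0.29, -0.26 and 1.38, and Ifi44, Rtp4, Rsad2 and Zbp1 differed by 0.77 (SE 1.32), 0.47 (SE 0.81), 0.44 (SE 0.86) and 0.22 (SE 0.31). Without the GFP-negative array of 631 the list turned, with a mean of -0.49 (adjusted p = 2.53e-05), without tumour 631 the mean was -0.15 (0.26; 0.0667 with the block), and without the GFP-positive array of 566 the mean was -0.10 (0.877). With the block and a common floor its adjusted p was 0.13.

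The list of p53 targets and retinoblastoma pathway genes rose relative to all genes, with a mean of 0.10, a median of 0.0053 and 11 of 21 higher (camera adjusted p = 0.0162; adjusted p = 0.647 with an estimated correlation). Zmat3, a p53 target, differed by 1.04 (SE 0.44) and was higher in all 4 tumours, as were Ccng1 and Trp53inp1, while 3 other members were lower in all 4; on the GFP-positive array of 573 Zmat3 was not well above the raised background. The call was lost without the GFP-positive arrays of 567 (0.893) or 631 (0.153), the GFP-negative array of 573 (0.704), tumours 567 (0.215) or 631 (0.0882; 0.096 with the block), and with the block and a common floor (0.135). G2 and mitosis genes had a mean of 0.05, with 18 of 28 higher (camera adjusted p = 0.0462; adjusted p = 0.451 with an estimated correlation), and Hmmr differed by 0.26, Ube2c by 0.19, Ttk by -0.16 and Ccna2 by -0.15. That call was lost without the GFP-negative arrays of 566 (0.439), 573 (0.0739) or 631 (0.23), the GFP-positive arrays of 567 (0.545) or 631 (0.262), tumours 566 (0.232), 567 (0.107) or 631 (0.34; 0.216 with the block). The median difference of all genes was -0.06.

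Other settings ended some of these calls. Without a filter on dim probes, camera's adjusted p was 0.249 for the basal list, 0.0772 for fibroblast markers, 0.915 for interferon response, 0.407 for interstitial matrix, 0.536 for mammary stem and cap cell, 0.915 for p53 targets, 0.415 for squamous and 0.527 for G2 and mitosis genes. With array weights it was 0.189 for S phase, 0.058 for endothelial, 0.121 for hypoxia and 0.211 for interferon genes. After quantile normalization it was 0.775 for S phase, 0.103 for endothelial and 0.0522 for mammary stem and cap cell genes. With a percentile over probes detected on all 8 arrays it was 0.0603 for S phase, 0.0527 for endothelial, 0.0578 for interferon and 0.0527 for mammary stem and cap cell genes. With a common floor the means of mammary stem and cap cell, interferon and cell adhesion genes were 0.17, 0.077 and 0.54, and camera's adjusted p was 0.0618 for G2 and mitosis, 0.164 for interferon, 0.0715 for mammary stem and cap cell and 0.0939 for squamous genes. With a filter of 3 of 4 arrays it was 0.201 for G2 and mitosis and 0.0944 for p53 targets, and with probes detected on all 8 arrays 0.0621 for G2 and mitosis and 0.112 for mammary stem and cap cell genes. The G2 and mitosis list also lost its call with median scaling (0.212) and normexp (0.216), where its mean was -0.053 and -0.010.

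**Figure D3:**
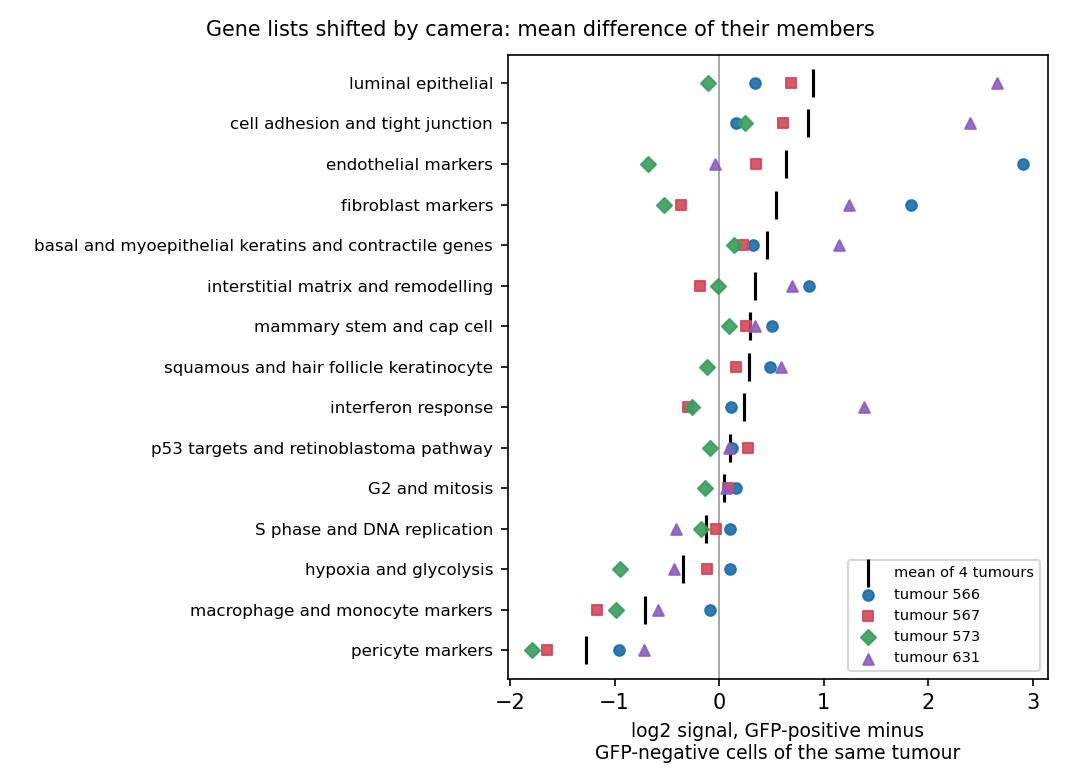
Mean log2 difference of the members of each of the 15 lists shifted by camera (vertical axis) between GFP-positive and GFP-negative cells (horizontal axis), with a coloured point per tumour and a bar at the mean of 4 tumours. The pericyte and macrophage lists lie below 0 in all 4 tumours, and the luminal list reaches 2.66 in tumour 631.

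The other lists did not pass camera's test, with mean differences between -0.13 and 0.24. Adjusted p was 0.0672 for basement membrane and hemidesmosome, 0.136 for epithelial-mesenchymal transition, 0.149 for granulocyte and mast cell markers, 0.221 for dissociation stress and immediate early genes, and 0.361 for each of cancer stem cell and pluripotency, antigen presentation and oxidative phosphorylation. It was 0.409 for hormone-sensing luminal, 0.411 for Schwann and neural, 0.427 for milk and alveolar, 0.461 for Hedgehog, 0.481 for Wnt, 0.592 for phosphoinositide 3-kinase, 0.605 for cytokine and chemokine, 0.772 for ribosomal protein, 0.923 for TGF-beta and BMP, 0.97 for Notch and 0.97 for skeletal muscle genes. Among their members, Notch4 differed by 1.39 (SE 0.55), Heyl by -1.11 (SE 0.50), Cxcl12 by 1.37 (SE 0.67), Stat5a by -0.49 (SE 0.22), Junb by -0.41 (SE 0.18), Gadd45b by -0.54 (SE 0.26) and Mpo by -1.03 (SE 0.49). In 9 of the 33 lists the mean, the median and the test differed in sign, in 0 of the 15 that shifted. Of 37 lists, 4 had too few measured members to test. The lymphocyte, erythroid and platelet, and adipocyte lists had 4 each, among them Cd4 at -0.21 (SE 0.17), Ppbp at 1.75 (SE 0.85) and Lpl at 0.55 (SE 0.90). The list of the transgene locus and sort markers had 2, Inpp5d and Itga6.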

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

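The tests of explanations for tumour 631 were chosen after its values had been seen, and the tests with other splits of the arrays before. A sample is given here where its gap to the nearest of its population's other 3 samples, over the whole range, exceeded Dixon's critical value for 4 samples. This held for 29 of 308 groups of 4 values, and chance gives about 1 in 20, or 15.4.

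The array of GFP-positive cells of tumour 573 gave 8 of the 29. Its share of gene spots well above background was 34.1% against 56.9% to 57.8% in the other GFP-positive arrays, its lowest signal 28.2 against 2.66 to 2.89 units, and the SD of its negative controls 55.5 against 3.14 to 3.71 units. Levels on it were low for Acod1 (-3.40), Cd44 (0.69), Inpp5d (-3.26) and Thy1 (-2.27), and for the mean of the interstitial matrix list (0.40 against 2.60 to 2.74). That list was also low on the GFP-negative array of 573, at 0.41 against 1.87 to 2.78 on the other GFP-negative arrays. Its low level is thus shared by both samples of this tumour.

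The GFP-negative cells of tumour 631 gave 11. Their levels were low for Aldh1a3 (-2.55), Cldn4 (-3.83), Krt7 (-1.54), Lama3 (-4.58), the prolactin receptor Prlr (-2.73), Rtp4 (-0.45), Sox10 (-1.58), Trp53inp1 (-0.98), and for the hormone-sensing luminal (-0.26) and the cell adhesion (-1.34) lists, and high for Rmrp (2.003). GFP-positive cells of 631 were low for Epcam (2.41), Ndufs1 (3.38) and the cell adhesion list (1.06). GFP-positive cells of 567 were low for Ppbp (-3.87) and the granulocyte list (-0.28). Of the GFP-negative cells, those of 567 were high for Muc1 (-0.74), those of 566 high for Egfl7 (1.19), and those of 573 low for Rptor (1.23), the phosphoinositide 3-kinase list (0.78) and the dissociation stress list (4.36).

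In tumour 631, 27 of 38 measured luminal or adhesion genes were over 2-fold higher in GFP-positive cells, against 0, 4 and 2 in 566, 567 and 573. A poor array is argued against by its share of gene spots well above background, 54.3%, within the range of the others. For non-epithelial cells in place of tumour cells, Krt8 and Krt18 were examined. Their mean difference in this pair was -0.20 beside a median of 3.61 for the luminal list, which goes against that explanation. They are only 2 genes, though, and 14 of the 20 measured luminal genes were over 2-fold higher in GFP-positive cells here. The rule was also written after these values had been seen, so it does not decide and the explanation stays open. Another candidate explanation is a more mesenchymal state of these GFP-negative tumour cells: 17 of 20 measured genes of the epithelial-mesenchymal transition list lay below the pair's median of all genes, but in tumour 573 only 3 did, as one-sided the other way, so it stays open. The shift was small: the list's mean in this pair was -0.25 and its median -0.40, beside -0.20 for the median of all genes. Mean levels of the list were high in both populations of 631, at 2.97 in GFP-positive and 3.22 in GFP-negative cells, against at most 2.63 on the other arrays. The rule for this test was changed after the 17 was seen: at first the count was of members lower in the pair, also 17, and that tumour alone decided, which would have spoken for the explanation.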

How the results depend on the processing

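The alternatives with a filter of 3 of 4 arrays, a percentile over probes detected on all 8 arrays, a common floor, the block without tumour 631, and the mammary stem and cap cell list without Inpp5d were chosen after the data were seen. So was the threshold of 0.1 with the random block. The others were chosen before. The count of genes called by limma was 14 with that threshold and block, and 0 under every other alternative run. At an unadjusted p under 0.05 it was 161, and 259 without a filter or with 3 of 4 arrays, 59 with probes detected on all 8 arrays, 1113 with the tumour as a fixed block, 1005 as a random block, 925 with the block after quantile normalization, 919 with the block and a common floor, and 1067 with the block without tumour 631. The count of shifted lists was 15 with the block and moved to 1 with an estimated correlation, 1 with fry, and 0 for each of these with the block; leaving out arrays or tumours gave 8 to 17. With the other settings as reported, the block on the tumour pairing kept the same 15 lists, while members passing when adjusted over the list alone went from 3 to 15. With a common floor the block lost the macrophage (0.388) and p53 (0.135) lists, which the floor alone kept, and kept the G2 and mitosis list, which the floor alone lost (0.0618). Without Inpp5d the mammary stem and cap cell list had a mean of 0.18 and lost its call (0.163; 0.267 with the block). The share of variance between tumours, 76.6%, was 70.2% after quantile normalization, 74.9% with the median, 79.3% with normexp, 54.3% without a filter, 78.7% with probes detected on all 8 arrays, 73.6% with 3 of 4 arrays, 81.6% with a common floor, and 73.2% to 75.6% without a tumour; the cause was not tested. The median difference of all genes, -0.06, moved to -0.16 with median scaling and to 0.19 without a filter, so that the tests of the G2 and mitosis list (mean 0.048) and the p53 list (mean 0.10) turned there.

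Differences that turned sign, none of them called for a single gene, were Lpl (-0.18) and Procr (-0.15) after quantile normalization with and without the block; Itga6 (-0.025), Ndufs1 (-0.024), Trp63 (-0.079) and the G2 and mitosis list (-0.053) with the median; and Itga6 (-0.034), Trp63 (-0.059) and the G2 and mitosis list (-0.010) with normexp. With array weights they were Ifi44 (-0.068), Itga6 (-0.11), Rtp4 (-0.069), Trp63 (-0.011) and the interferon list (-0.24). With the mean of a gene's probes they were Cd44 (0.061), Itga6 (-0.24) and Ttk (0.015), and with the common floor, with and without the block, Lpl (-0.093). With the block without tumour 631 they were Cd24a (-0.064), Lep (0.024), Rsad2 (-0.062), Rtp4 (-0.069) and the interferon list (-0.15). Leaving out arrays or tumours gave ranges that crossed 0: Cd24a -0.15 to 1.23, Cd44 -0.53 to 0.29, Egfl7 -0.19 to 1.31, Emcn -0.015 to 2.75, Eng -0.10 to 1.24, Ifi44 -0.60 to 1.45, Itga6 -0.18 to 0.33, Krt18 -0.029 to 0.30, Lep -0.23 to 0.024, Lpl -0.010 to 1.35, Mbp -0.23 to 1.46, Ndufa4 -0.021 to 0.60, Prlr -0.074 to 1.41, Procr -0.35 to 1.64, Rpl27 -0.38 to 0.0037, Rsad2 -0.35 to 1.06, Rtp4 -0.41 to 0.81, Sox10 -0.26 to 1.53 and Trp63 -0.092 to 0.14. For lists such ranges were -0.49 to 0.62 for interferon response, -0.11 to 0.91 for interstitial matrix, -0.12 to 1.07 for endothelial markers, -0.011 to 0.11 for G2 and mitosis and -0.024 to 0.28 for p53 targets. The range for hypoxia and glycolysis, -0.49 to -0.079, did not cross 0, but its test turned at -0.079. Of 117 named genes, 81 moved by over 1.5 times or turned when 1 array was left out, among them Gas6 (0.047 without the GFP-negative array of 631), Thy1 (-0.24 without the GFP-positive array of 573) and Dcn (0.40 without the GFP-negative array of 573). The cause was not tested for any of these. The epithelial-mesenchymal transition list, not called, was higher without the GFP-negative array of 631 (adjusted p = 0.000187) and lower without that of 573 (adjusted p = 0.0263). The pericyte and macrophage lists stayed called with each array and each tumour left out. Genes at the common floor on all arrays gave no value. A slide block was not run, since there was 1 slide, nor the series-wide table, whose values are identical; normexp used median spot signals, as the columns used here hold no mean signal. The raised background of the GFP-positive array of 573 limits what can be seen of dim genes.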

Other observations

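The tests of explanations for the structural RNAs and the pericyte markers were chosen after those values had been seen, and the tests with other splits of the arrays before, though how their shares are read was changed after.

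Structural non-coding RNAs, a set put together after the values had been seen, were lower in GFP-positive cells on average. Of 25 tested, 25 had a lower mean and 17 were lower in all 4 tumours; 7 of the 17 had been named for that direction and raised the pattern, and among the other 18 the count was 10, with near-identical RNAs among them, so that no chance count is given. An unadjusted p under 0.05 was seen for 16, and none passed limma's test without a block. Their median differences were -0.86, -0.96, -0.64 and -1.81 in 566, 567, 573 and 631. Tumours also differed in how many genes lay over 2-fold apart between populations, with 321 higher and 235 lower in 566, 186 and 561 in 567, 1002 and 441 in 573, and 1005 and 357 in 631. In 573 the raised background of the GFP-positive array can lift dim genes, so part of its 1002 may come from that background. With the tumour as a random block, which assumes a correlation of 0.657 within tumours, 14 genes had a limma adjusted p under 0.1. Of these 13 were lower, among them Rprl2, Rprl3, Dlk1, Higd1b, Rgs5, Rn7sk, Rpph1, Gucy1a1 and Rn7s1, and Gzme was higher at 4.95 (limma adjusted p = 0.0681), against signal well above background on 1 of 4 GFP-negative arrays. This threshold was paired with the random block after the values had been seen. Without a block and with a fixed block, 0 genes reached it. The structural RNAs named here had raised the pattern, so they add no separate support.

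Scaling between arrays is argued against as the whole cause of the lower structural RNAs. Their median difference was -1.10 where that of all genes was -0.06. With normexp it was -0.71, the smallest in size under 4 other scalings, where that of all genes was -0.08. Scaling by the median or by the spike-in probes subtracts 1 value per array and so moves all genes alike. The -1.78 with the spike-in probes therefore includes a shift of all genes and adds no evidence here. A loss shared by all transcripts without a poly(A) tail is argued against by the replication-dependent histone transcripts, which also lack it. Over 42 of these genes the median difference was 0.011 and 0 were lower in all 4 tumours. A loss of only some transcripts without a tail was not tested. The position on the slide cannot be told apart from the populations, since 0 slide columns held arrays of both. Signal of 7 spike-in probes was higher on the GFP-positive array of every pair, by 0.17 to 0.88. A difference in RNA input or labelling and a difference between the sorted cells themselves were not tested and stay open.

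A lower share of epithelial cells in the GFP-negative preparations would raise other cell types' markers alike only if all of them made up for it alike. In that form, as the whole cause of the lower pericyte list, it is argued against by the fibroblast list. That list lay above the pericyte list in all 4 tumours, by 2.79, 1.28, 1.26 and 1.96, with a mean of 1.82 (SD 0.72). At first the fibroblast mean, 0.55, had been compared with 0. A lower epithelial share made up by some cell types alone was not tested. A part of the shared form stays open. The macrophage list also fell (-0.70, and -0.17 with a common floor), and the fibroblast means were -0.36 and -0.52 in 567 and 573. Pericytes in the GFP-negative preparations stay open: 7 of the 12 measured markers were lower in GFP-positive cells of all 4 tumours, where chance gives 0.75 if they moved independently, but that count raised the explanation, and not every marker followed, with -0.17 for Mcam, -0.16 for Notch3 and 0.096 for Angpt2. Cspg4, at -0.18 on average, was higher in 573 and 631, by 0.19 and 0.995, and Des was higher in 573 by 0.087. At first more than 6 of the 12 was to be enough, which would have spoken for pericytes, and now all are needed; tumour cells that express these genes are not excluded, and the lineage antibodies, which the labels do not name, could have removed pericytes.

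Other splits of the 8 arrays into groups of 4 tested whether the groups could arise by chance. For the shift of the pericyte list 1 of 35 splits, the real one, reached its mean difference of 1.28 in size, and the highest other gave 1.08. The arrays are paired, though, and only 8 splits part all 4 pairs, too few for a share under 0.05; the highest other of those gave 0.92. At first a share under 0.05 of the 35 was to be enough. For the count of genes, 35 of 35 splits reached the real 0, as any split must, so that comparison says nothing about chance; the highest other gave 3609. For genes at an unadjusted p under 0.05, 28 splits reached the real 161 and the highest other gave 6781. All of these but the real one keep both arrays of some tumours on the same side, so differences between tumours enter their counts. That share therefore does not decide about chance. Chance cannot be excluded for the count of lists, where 9 splits, the real one included, gave at least the real 15 and the highest other gave 24. The split that called 3609 genes set tumours 566 and 573 against 567 and 631 and so points to the differences between tumours; 2 splits called any genes. Among splits that part all 4 pairs, the others gave at most 17 lists and 129 genes at an unadjusted p under 0.05. The real 161 was thus the highest of those 8, too few for a share under 0.05, so chance is not excluded there either. With the tumour as a block, 2 of those 8, the real one included, gave at least the real 15 lists, and the others gave at most 17. For genes at an unadjusted p under 0.05, 2 of the 8, again with the real one, gave at least the real 1113, and the others at most 1363.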
